A study of Mus musculus with 8 samples.

How the data were processed

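RNA was measured in CD44+ CD4+ T cells, the antigen-experienced helper T cells, sorted from skin-draining lymph nodes of mice on the BALB/cAJcl background. Per the labels, the mice were wild type (WT), lacked T-bet, lacked STAT6 or lacked both, and the sorted cells received PMA with ionomycin over 2 h before RNA was taken. PMA and ionomycin together bypass the T cell receptor and bring out the cytokines that a cell is poised to make. Each of the 4 genotypes had 2 libraries, 8 in all, and each library was placed in its genotype by its own label. The genotypes are called WT, T-bet-null, STAT6-null and double-null.

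The deposited table holds FPKM values, in which fragments per transcript are scaled to transcript length and to the mapped fragments of the library, with 1 column per library. Per the submitters' processing notes, Cufflinks and the mouse genome build mm10 were used. The aligner, the Cufflinks version and the strandedness are not given in the sources used here. The gene annotation was RefSeq, as the table's own name states. All 11906 lines of the table lay above 0.1 FPKM in all 8 libraries. A gene silent in any library is therefore missing from the table, and no statement is made about such genes. For the 43 symbols that stood on several lines, the line with the highest mean was used and 65 lines were set aside, which left 11841 symbols. A further 17 lines carried names that spreadsheet software had turned into dates; they were counted in the totals and not named. Of the symbols, 10575 matched the RefSeq gene table of assembly GRCm38, the assembly that mm10 is drawn from, and 1164 more matched through an older name. Coordinates come from that table, count from 1 and span the whole gene, and the FPKM of a gene covers all of its annotated exons.

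Sequencing depth is not printed in the table, so it was estimated from the steps of low values. A gene with few fragments takes values that are whole multiples of the value of 1 fragment, and ratios between libraries then fall on simple fractions. Over 503 genes under 0.5 FPKM, with a tolerance of 0.001 on the log2 scale, the relative depth of the libraries ranged from 0.891 to 1.081, a ratio of 1.214 between the deepest and the shallowest. At these depths 76 of the 503 genes had whole multiples in all 8 libraries, against 0 at shifted depths. The value of 1 fragment in 5 genes with a single annotated transcript gave an approximate depth of the reference library, 17.7 in units of 1000 x 1000 fragments (quartiles 16.1 and 18.8). Most genes did not fall on whole steps, so no count test was run. At this depth the SD between replicates, on the log2 scale, was 0.079 to 0.106 for genes of 16 to 64 FPKM, depending on genotype. The squared difference of the replicates over the counting variance had a mean of 2.23 in T-bet-null, 3.69 in STAT6-null, 7.11 in double-null and 7.67 in WT libraries. The medians were 0.87, 1.23, 2.51 and 2.37 in that order, against 0.455 if only counting error were present, so no pair was counted as 1 library. These ratios use the approximate depth and the longest transcript of each gene.

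Tests were run with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1). A gene was tested if it had at least 1 FPKM in at least 2 libraries, which left 10281 genes. All 8 libraries entered 1 fit with a mean per genotype, 4 residual degrees of freedom and empirical Bayes moderation with an intensity trend. The limma tests of genes were two-sided, the Fisher exact tests of the closing section were one-sided, and limma p-values were adjusted by the Benjamini-Hochberg method within each of 6 comparisons. A gene was called at an adjusted p under 0.05. The comparisons were each mutant against WT, the double-null cells against each single mutant, and the interaction of the genotypes. The interaction is the effect of STAT6 loss in T-bet-null cells minus its effect in T-bet-sufficient cells. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes such as Il9. Means are given with the SD over n = 2 libraries. Nothing in the labels says that the libraries of a genotype came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. Other tools were Python 3.11.15 with pandas 2.3.3 and SciPy 1.17.1.

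There were 26 gene lists with 438 entries: Th1, cytotoxic effector, Th2, Th9, Th17, Treg, Tfh, naive and central memory, skin homing and tissue residence, interferon response, IL-4 and STAT6 response, IL-2 and STAT5 response, activation-induced immediate early, cell cycle, glycolysis, heat shock and dissociation stress, unfolded protein response, Y-linked genes with Xist, and markers of B cells, CD8 T cells, myeloid and dendritic cells, NK and other innate-like T cells, mast cells and basophils, stroma and endothelium, keratinocytes and erythroid cells. A list was tested when at least 3 of its genes were tested, which held for 22 lists. The Th1 list holds Tbx21, whose fall in cells that lack T-bet follows from the design. The test was camera from limma with a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. It was repeated with an estimated correlation, which with 4 residual degrees of freedom is poorly determined. The self-contained test fry, which asks if members change and not if they change more than other genes, was run on the same lists. A list is said to pass by camera only. Fry passed several lists that camera did not. For T-bet-null against WT these included Th1 (fry adjusted p = 0.000141) and Th2 (fry adjusted p = 0.000243). Th9 (fry adjusted p = 0.183) passed neither there. These fry values ask if members move together in 1 direction. Without regard to direction, fry gave Th9 an adjusted p = 4.1e-06 in that comparison. In 1 direction, fry passed Th9 in STAT6-null (fry adjusted p = 0.0346) and double-null cells (fry adjusted p = 0.011) against WT. Counts of members are given over all genes tested and adjusted over the list alone. Where only 1 count is given, both were the same.

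Genes are named by a rule with 3 parts. It takes 21 core genes, of which 20 were tested (Spi1 was not analysed here). It adds, per comparison and direction, the 8 called genes with the largest change whose compared libraries did not overlap, and per list up to 4 members with the smallest p. Immunoglobulin and T cell receptor segments, predicted genes and small RNA genes were counted but not named. Some genes that the rule selects were tested and counted like the others and are not reported here. The groups, the comparisons, the test, the lists, the rule for named genes and the alternatives listed in the next paragraph were fixed before the data were examined, except for those described there as added. FPKM of Il22 and Iltifb, of the haemoglobin genes, of Rps27, of Hspa1a and Hspa1b and of the guanylate-binding proteins depends on how reads shared with near-identical copies were assigned, and these values are uncertain for that reason.

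The alternatives were pseudocounts of 0.1 and 0.25, no filter and a filter of 5 FPKM, median-of-ratios scaling, quantile normalization, a fit without the intensity trend, robust empirical Bayes, library weights, only the compared genotypes, the replicate number as a block, leaving out short RNA and receptor segment genes, an adjusted p under 0.1, an added 2-fold limit, and leaving out each library in turn. Added after the data were seen were a fit without the WT libraries, a fit without Y-linked and haemoglobin genes, a fit of the 9304 genes with known GC content and transcript length after trends on both were removed, and a comparison of mutant changes with 1 WT library for each mutant. The fit was checked on simulated data with the real gene means and spread and 200 changed genes among the 10281, none of them drawn from the genes of lowest mean. Changes of 1 and 2 on the log2 scale were recovered in 100% of genes in each comparison. A change of 0.5 was recovered in 94.1% of genes for T-bet-null against WT, 97.1% for STAT6-null against WT, 95.6% for double-null against WT, 89.7% for double-null against T-bet-null, 97.1% for double-null against STAT6-null and 54.4% for the interaction. False calls made up 2%, 7.5%, 4.8%, 8.5%, 4.3% and 4.5% of the calls in the same order. The simulated data had few changed genes and independent errors, whereas most genes of the real data were called against WT. These rates may therefore not hold for the real data or for low genes. Comparisons that share the WT libraries were set beside 50 simulations in which all libraries, WT included, were drawn without any change.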

Results

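Tbx21, which encodes T-bet, the factor that drives Th1 development, and Stat6, which carries the signal of IL-4 and IL-13, were first read in every library. Tbx21 (mm10 chr 11, 97098007-97115331) stood at 30.8 and 31.6 FPKM in the WT libraries, 1.44 and 1.54 in the T-bet-null, 102 and 92.1 in the STAT6-null and 2.49 and 2.09 in the double-null libraries. Stat6 (chr 10, 127642955-127660987) stood at 89.9 and 90.9, 88.8 and 89.8, 31.6 and 29.0 and 29.6 and 26.9 FPKM in the same order. Each targeted transcript was thus lowest in the 4 libraries labelled as lacking it, and neither was absent there. Which exons were removed is not given in the sources used here.

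Il9, whose product supports mast cells and type 2 inflammation (chr 13, 56479277-56482257), was close to absent in WT cells at 0.314 ± 0.261 FPKM (mean ± SD, n = 2). It stood at 7.86 ± 1.27 FPKM in T-bet-null, 4.58 ± 0.0564 in STAT6-null and 16.03 ± 0.258 in double-null cells, the highest of the 4 genotypes. Il9 values lay on whole steps, read here as single fragments, to within 0.042 of a step. The steps were 1 and 4 in the WT, 46 and 65 in the T-bet-null, 34 and 36 in the STAT6-null and 115 and 130 in the double-null libraries. Per depth, Il9 was 24.9 times the WT level in T-bet-null (95% interval 10.4 to 78.2), 14.4 times in STAT6-null (5.9 to 45.8) and 50.5 times in double-null cells (21.3 to 157). It was 2.03 times higher in double-null than in T-bet-null cells (1.61 to 2.56) and 3.5 times higher than in STAT6-null cells (2.67 to 4.63). These intervals hold counting error only and not the spread between libraries. The other cytokine genes followed first here lie on mm10 at chr 11, 53612460-53618665 (Il4), 53631323-53634702 (Il13) and 53720794-53725103 (Il5), and at chr 10, 118441046-118445894 (Ifng) and 118204584-118210047 (Il22). Il17a lies at chr 1, 20730905-20734496, Il17f at chr 1, 20777146-20785274, and Il10 at chr 1, 131019845-131024970.

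**Figure D1:**
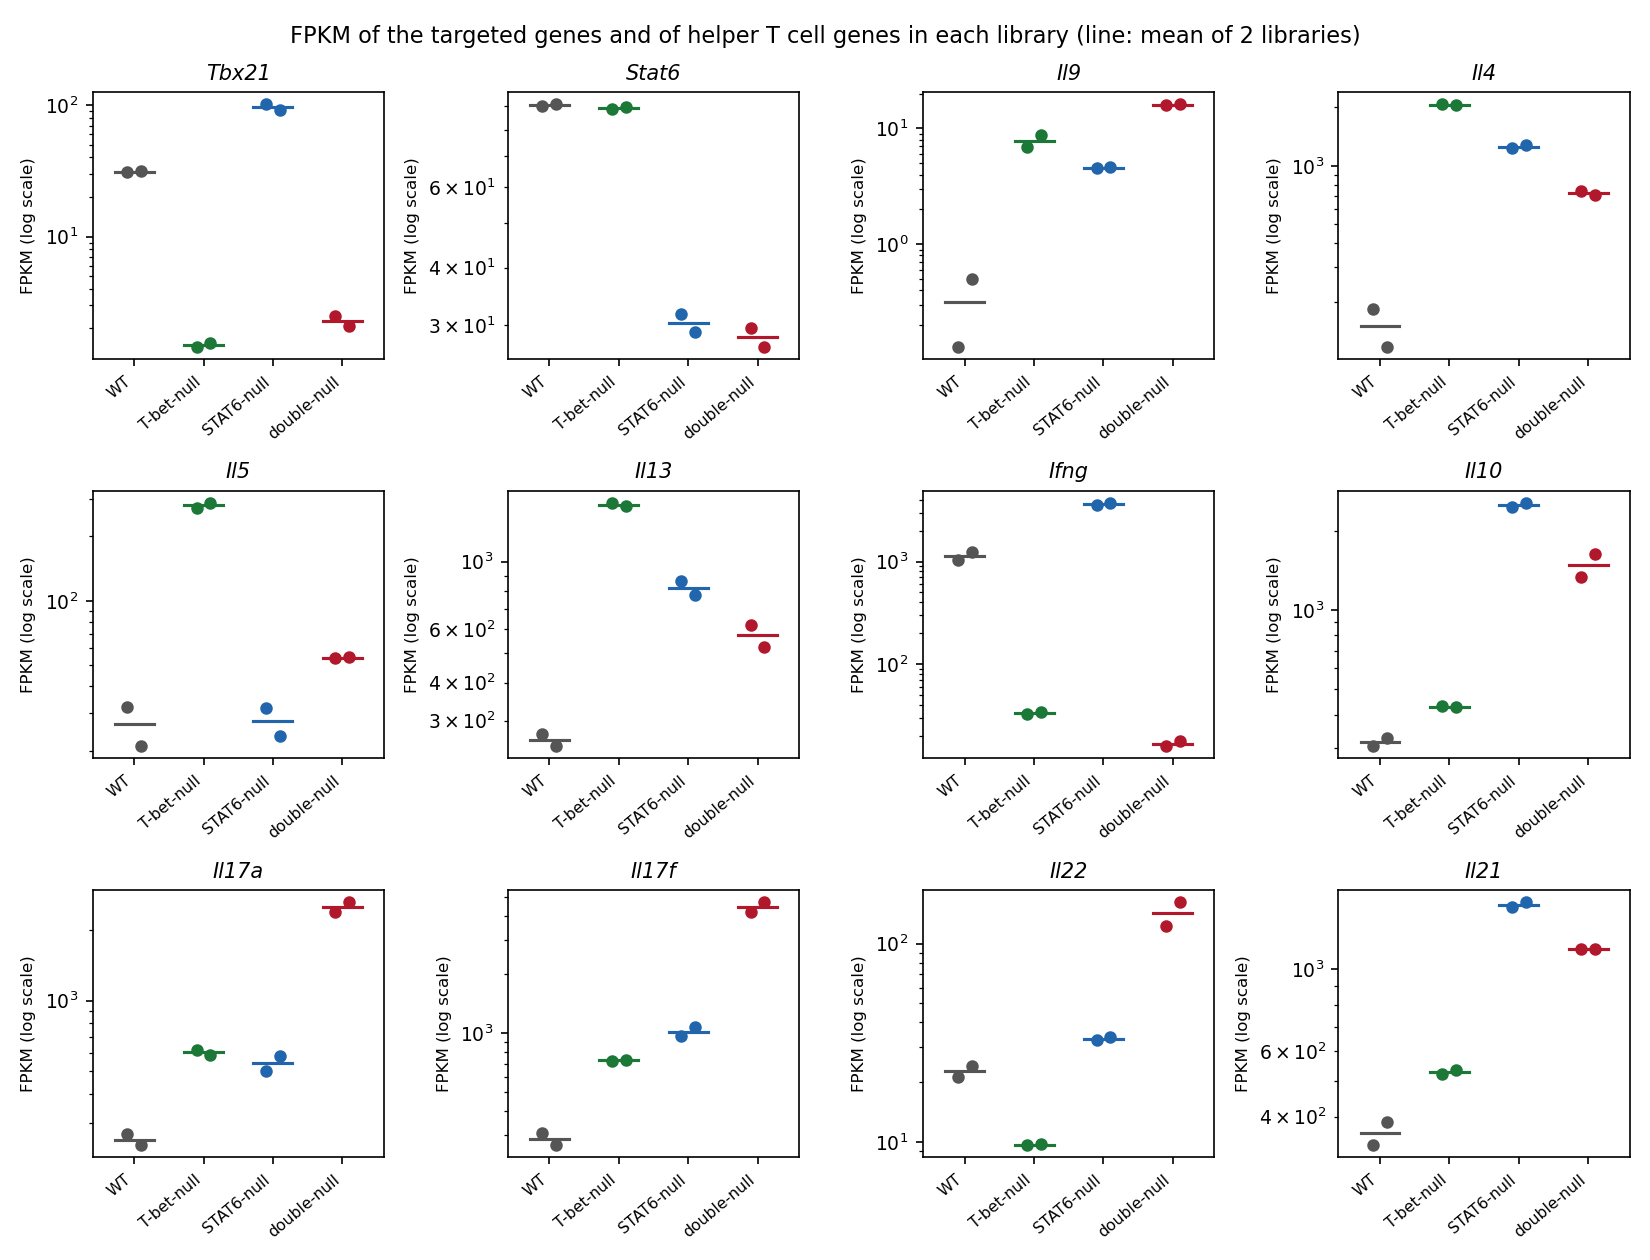
FPKM of 12 genes (log axis) in each library by genotype, with a line at the mean of 2 libraries. Il9, Il17a, Il17f and Il22 are highest in the double-null libraries, Il4, Il5 and Il13 in the T-bet-null libraries, and Ifng, Il10, Il21 and Tbx21 in the STAT6-null libraries.

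The 8 libraries separated by genotype. Pearson r of log2(FPKM + 1) was 0.9971 to 0.9979 within genotypes, 0.9865 to 0.9912 between mutant genotypes and 0.9492 to 0.9642 between WT and mutant libraries. The WT libraries therefore stood apart from all 3 mutants. The labels give neither sex nor batch, so each comparison with WT below may hold a difference in how WT was prepared as well as the loss. Of the 10281 genes tested, 2780 were called higher and 2795 lower in each of the 3 mutants than in WT. Simulations in which all 8 libraries, WT included, were drawn without any change gave 0 such genes, which is nearly certain where nothing changes. If the calls were independent, 446.3 and 495 would be found. The changes of T-bet-null and STAT6-null cells against WT had r = 0.844, against 0.4985 in those simulations, where the shared WT libraries alone make the changes alike. The covariance was 0.3153, against 0.0044 in the simulations. With 1 WT library for each mutant, so that no control was shared, r was 0.814 and 0.818 in the 2 ways to assign them, a choice made after the likeness was seen. Neither the simulations nor this split bears on an offset that both WT libraries share.

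How did T-bet-null cells differ from WT? In T-bet-null cells the type 2 cytokine genes rose: Il4, the inducer of Th2 cells and of class switching to IgE, from 149.9 ± 46.7 to 2064 ± 21.3 FPKM (log2 fold change 3.81, adjusted p = 2.97e-07, n = 2 per genotype). Il5, the growth factor of eosinophils, rose from 26.5 ± 7.84 to 279 ± 9.55 FPKM (3.37, adjusted p = 9.04e-07), and Il13, an effector of mucus and skin barrier change, from 259 ± 16.3 to 1539 ± 24.5 (2.57). Il9 rose by 2.76 ± 0.136 (log2 ± SE, adjusted p = 5.67e-07). Ifng, the Th1 cytokine, fell from 1139.5 ± 157 to 33.1 ± 1.05 FPKM (-5.06, adjusted p = 2.11e-08), and Cxcr3, a T-bet target that guides Th1 cells to inflamed tissue, from 118 ± 12.8 to 7.69 ± 0.787 (-3.77). In all, 3518 genes were higher and 3737 lower of 10281 tested, and 856 of these 7255 changed at least 2-fold.

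Among the largest rises in T-bet-null cells were Mmp13, a collagen-degrading enzyme (2.20 to 22.4 FPKM, log2 2.87), Cysltr1, a leukotriene receptor of type 2 cells (1.14 to 11.2, 2.52), the calcium sensor Ncs1 (2.84) and AA465934 (2.90 to 35.8, 3.23). Il17a and Il17f, which recruit neutrophils through epithelium, rose by 1.23 and 1.33, while Il22, which acts on keratinocytes, was lower (-1.15). Il10 (0.45), Il21 (0.55), Il2 (0.72), Gata3, the Th2 factor (0.88), and Irf4 (0.56) rose less. Csf2 (-1.09), Bcl6, the factor of follicular helper cells (-1.16), and Tnf (-0.34, adjusted p = 0.00365) fell, and the Tnf call was lost with quantile normalization (adjusted p = 0.101). Foxp3, the Treg factor, gave 0.09 (adjusted p = 0.294), and was called with the GC and length trends removed (0.176, adjusted p = 0.0321), while Stat6 gave -0.02 (adjusted p = 0.819). Arl5c (-2.82), Mxd4 (-2.40) and Arl13b (-2.30) fell, as did the haemoglobin genes Hba-a1 (169 ± 85.1 to 3.50 ± 0.0508 FPKM, -5.15) and Beta-s (163 ± 69.2 to 3.92 ± 0.142, -5.00), which mark red blood cells.

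As a group, interferon response genes were lower in T-bet-null cells (1 higher and 26 lower of 29, median -0.995, adjusted p = 2.15e-07), among them the guanylate-binding proteins Gbp4 (-1.33) and Gbp3 (-1.01) and Irgm1 (-1.70), which act in defence inside cells. With an estimated correlation the interferon list had an adjusted p = 0.637. Immediate early genes of T cell activation were lower (2 higher and 22 lower of 27, median -0.52, adjusted p = 0.000299), such as Fosb (-1.78), Egr3 (-1.69), Dusp1 (-1.25) and Nr4a2 (-1.12). The immediate early list had an adjusted p = 0.637 with an estimated correlation. Cell cycle genes were lower by small amounts (0 higher and 23 lower of 29, median -0.30, adjusted p = 0.0017), including Pcna (-0.60), Mcm4 (-0.43) and Nusap1 (-0.71). The cell cycle list had an adjusted p = 0.637 with an estimated correlation.

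The other lists did not pass in T-bet-null cells. For helper subsets these were Th1 (5 higher and 11 lower of 18, median -0.61, adjusted p = 0.0813), Th2 (9 higher and 4 lower of 16, median 0.79, adjusted p = 0.0813) with Ccr4, a skin-homing receptor, at 1.31, and Th17 (10 higher and 3 lower of 15, median 0.55, adjusted p = 0.101) with Ccl20 at 1.22 and Ahr at 0.81. Th9 genes went both ways (5 higher and 6 lower of 15, median -0.12, mean 0.15, test downward, adjusted p = 0.937): Batf, a factor needed for Il9 transcription, was at 0.83 and the receptor gene Il9r at -0.70. Treg (8 higher and 6 lower of 19, median 0.09, adjusted p = 0.846) included Socs2 (1.31), Il2ra (0.78), Itgae (-1.02) and Ebi3 (-1.54), and Tfh (7 higher and 7 lower of 14, median -0.01, mean 0.18, test upward, adjusted p = 0.937) included Pou2af1 (1.08). Cytotoxic effector genes (0 higher and 7 lower of 11, median -0.36, adjusted p = 0.101) included Nkg7 (-1.83), Ctsw (-1.65) and Prf1, which encodes perforin (-0.80). Naive and central memory genes (4 higher and 10 lower of 16, median -0.69, adjusted p = 0.102) included Cd27 (-1.22), Dapl1 (-1.68) and Ccr7, the lymph node entry receptor (-1.44). Skin homing and tissue residence (4 higher and 11 lower of 17, median -0.39, adjusted p = 0.138), IL-4 and STAT6 response (5 higher and 7 lower of 14, median -0.19, mean 0.07, test downward, adjusted p = 0.937) and IL-2 and STAT5 response (8 higher and 5 lower of 16, 8 and 6 adjusted over the list alone, median 0.19, adjusted p = 0.327) did not pass.

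Housekeeping and stress lists in T-bet-null cells gave glycolysis (6 higher and 5 lower of 15, median -0.11, mean 0.04, test upward, adjusted p = 0.937) with Hk2 at 1.35, heat shock (8 higher and 3 lower of 12, median 0.45, adjusted p = 0.0813) with Hmox1 at 1.53 and Hspd1 at 0.91, and the unfolded protein response (2 higher and 6 lower of 12, median -0.18, adjusted p = 0.416). Lists of other cell types gave B cell (0 higher and 3 lower of 8, 0 and 1 adjusted over the list alone, median -0.51, adjusted p = 0.23), myeloid (0 higher and 6 lower of 8, median -0.89, adjusted p = 0.0813) with Lyz2 at -1.44 and Ctss at -1.11, and NK and innate-like markers (1 higher and 2 lower of 3, median -0.62, adjusted p = 0.897). The keratinocyte list rests on 3 genes (2 higher and 1 lower of 3, median 1.27, adjusted p = 0.274): Perp, a p53 target of cell adhesion (1.96), Dsp, a desmosome gene (1.27), and Sfn, a cell cycle inhibitor (-0.76), none of which is specific to skin. Y-linked genes were lower in each library of the mutant than in WT (0 higher and 4 lower of 4, median -1.41, adjusted p = 0.101). Of 4 lists with 1 tested gene, CD8 had Cd8b1 (-0.37, adjusted p = 0.0415), stroma and endothelium Pecam1 (-1.21), mast cells and basophils Kit (-1.04) and erythroid cells Hba-a1. The Y-linked list passed when double-null replicate 1 (adjusted p = 0.0154) or replicate 2 (adjusted p = 0.0157) was left out, which alters the shared variance only.

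**Figure D2:**
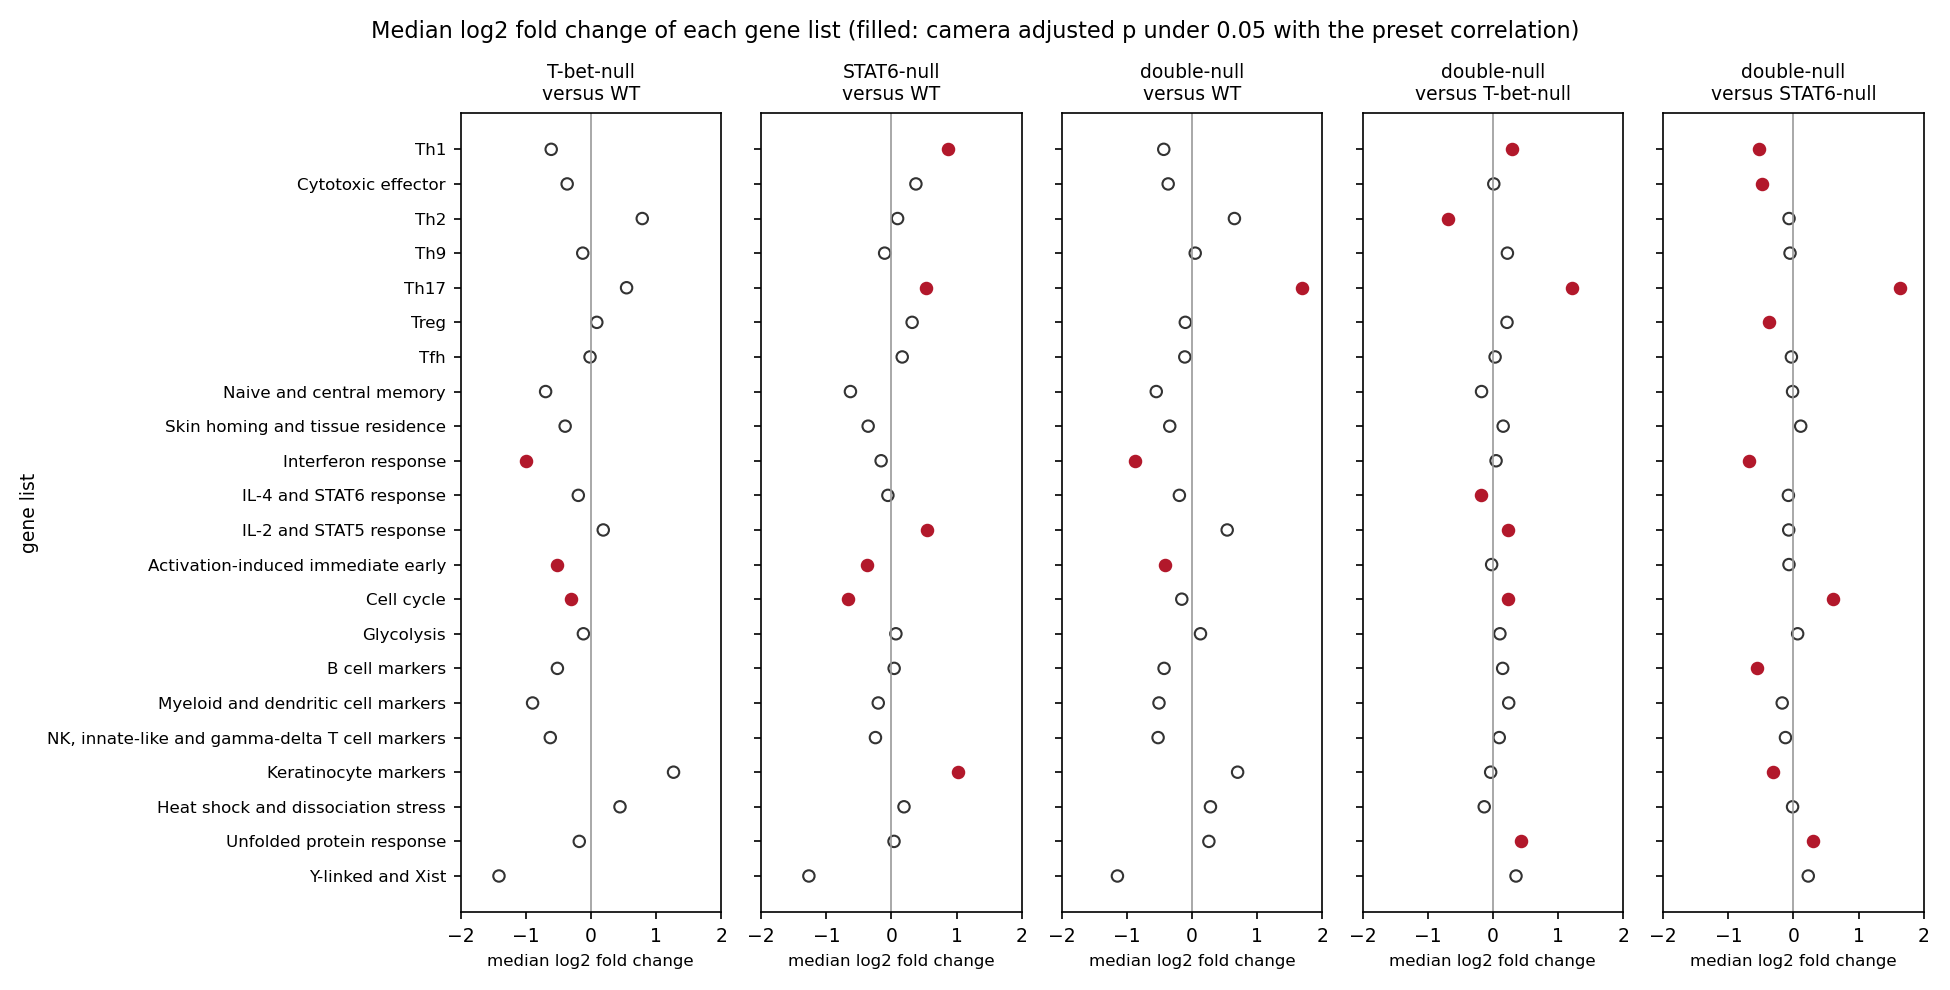
Median log2 fold change of the tested members of 22 gene lists (x axis) in 5 comparisons, filled where camera with the preset correlation passed at an adjusted p under 0.05. The Th17 list has its largest medians in double-null cells, 1.68 against WT and 1.63 against STAT6-null cells.

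How did STAT6-null cells differ from WT? STAT6-null cells had more of the Th1 genes Ifng and Tbx21: Ifng rose from 1139.5 ± 157 to 3610.0 ± 133 FPKM (log2 fold change 1.67, adjusted p = 8.43e-07, n = 2 per genotype) and Tbx21 from 31.2 ± 0.586 to 97.0 ± 6.93 (1.60). Il4 and Il13, whose induction in Th2 cells runs through STAT6, also rose, to 1257 ± 26.2 (3.09, adjusted p = 6.72e-07) and 819.8 ± 63.7 FPKM (1.66), while Il5 gave 27.6 ± 5.89 FPKM (0.07, adjusted p = 0.751). Il9 rose by 2.10 (adjusted p = 1.88e-06). Il10, an inhibitor of inflammation, rose from 315 ± 14.8 to 2504 ± 59.4 FPKM (2.99), and Gzmb, which encodes the killing enzyme granzyme B, from 13 ± 0.185 to 136 ± 2.50 (3.29). In all, 3591 genes were higher and 3709 lower of 10281 tested, and 1039 of these 7300 changed at least 2-fold.

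Besides Gzmb and Il4, large rises in STAT6-null cells were those of Fam20a, a secreted pseudokinase (0.154 to 22.0 FPKM, log2 4.32), Mmp13 (38.0 FPKM, 3.61), Sema7a, a semaphorin that acts on monocytes (12.8 to 146, 3.41), the protease inhibitor Timp1 (0.799 to 17.5, 3.38), Coro2a (3.28) and Chn1 (3.17). Il21 (2.05), Il17f (1.82), Il17a (1.07), Csf2 (0.91), Irf4 (0.62), Il2 (0.58), Il22 (0.53) and Foxp3 (0.40) rose, while Bcl6 (-1.37) and Gata3 (-0.31) fell. Tnf gave -0.17 (adjusted p = 0.0738, and 0.0332 without double-null replicate 1 and 0.0336 without double-null replicate 2). Stat6 itself fell by log2 1.55. The largest falls were those of Beta-s (-5.72), Hba-a1 (-5.59), the Myc antagonist Mxd4 (48.7 to 6.58 FPKM, -2.72), Ng23 (-2.68), Sytl1 (-2.55), the quiescence factor Klf4 (43.3 to 7.41, -2.39), Arl13b (-2.39) and Evl (-2.25).

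As a group, Th1 genes were higher in STAT6-null cells (12 higher and 3 lower of 18, median 0.86, adjusted p = 0.0116), among them the receptor genes Havcr2, which encodes the checkpoint TIM-3 (2.43), Cxcr6 (1.35) and Il18rap (1.33). The Th1 list had an adjusted p = 0.817 with an estimated correlation. Th17 genes were higher (8 higher and 2 lower of 15, median 0.53, adjusted p = 0.0404), with Ccl20, the ligand that draws CCR6-bearing cells into skin, at 2.42. The Th17 list had an adjusted p = 0.817 with an estimated correlation. That call was lost without WT replicate 1 (adjusted p = 0.0566), without STAT6-null replicate 2 (adjusted p = 0.0528) and at a filter of 5 FPKM (adjusted p = 0.0825). IL-2 and STAT5 response genes were higher (12 higher and 3 lower of 16, median 0.55, adjusted p = 0.0222), such as Socs2 (2.28), Prdm1 (1.42) and Il2ra (1.15). The IL-2 response list had an adjusted p = 0.817 with an estimated correlation and 0.0825 at a filter of 5 FPKM. The 3 keratinocyte-list genes Perp (2.43), Dsp (1.01) and Sfn (0.93) were higher (3 higher and 0 lower of 3, median 1.02, adjusted p = 0.0404). Their adjusted p = 0.817 with an estimated correlation, 0.0566 without WT replicate 1 and 0.0752 with no filter.

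Cell cycle genes were lower in STAT6-null cells (0 higher and 28 lower of 29, median -0.67, adjusted p = 2.1e-06), including Ccnb2 (-1.35), Rrm2 (-1.05), Mcm6 (-0.86) and Pcna (-0.76). The cell cycle list had an adjusted p = 0.817 with an estimated correlation. Immediate early genes were lower (4 higher and 18 lower of 27, median -0.38, adjusted p = 0.0116), including Fosb (-2.01), Egr3 (-1.99) and Nr4a2 (-1.57). The immediate early list had an adjusted p = 0.892 with an estimated correlation. Naive and central memory genes (4 higher and 12 lower of 16, median -0.63, adjusted p = 0.0572) did not pass, though Tcf7 (-1.42), Ccr7 (-1.80) and Dapl1 (-1.94) each fell. That list passed without STAT6-null replicate 1 (adjusted p = 0.0248), with median-of-ratios scaling (adjusted p = 0.0405) and with quantile normalization (adjusted p = 0.0304).

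The other lists did not pass in STAT6-null cells. Th2 genes went both ways (7 higher and 6 lower of 16, median 0.09, adjusted p = 0.777), with Maf, an activator of Il4, at 1.52 and the chemokine receptor gene Ccr8 at -1.33. Th9 genes did too (6 higher and 4 lower of 15, median -0.10, mean 0.13, test upward, adjusted p = 0.825), with Batf at 1.64, Irf8 at 1.49, Il9r at -1.43 and Il17rb at -2.16. Treg (10 higher and 7 lower of 19, median 0.32, adjusted p = 0.349) included Tigit (1.49), and IL-4 and STAT6 response (3 higher and 5 lower of 14, median -0.06, adjusted p = 0.548) included Ecm1 (-1.25) and Prkca (-0.998). Interferon response genes were split (8 higher and 12 lower of 29, median -0.16, adjusted p = 0.777), with Gbp5 at 1.91, the RNA sensor Ifih1 at 1.47 and Ifit1 at -0.93. The rest were cytotoxic effector (6 higher and 4 lower of 11, median 0.38, adjusted p = 0.777), Tfh (6 higher and 6 lower of 14, median 0.16, adjusted p = 0.769) and skin homing and tissue residence (4 higher and 11 lower of 17, median -0.36, adjusted p = 0.166). Glycolysis (6 higher and 6 lower of 15, median 0.07, adjusted p = 0.777) included Hk2 at 1.75, beside heat shock (6 higher and 3 lower of 12, median 0.19, adjusted p = 0.365) and the unfolded protein response (2 higher and 3 lower of 12, median 0.04, adjusted p = 0.953). Markers of other cells were B cell (0 higher and 0 lower of 8, median 0.04, adjusted p = 0.953), myeloid (1 higher and 4 lower of 8, median -0.20, adjusted p = 0.729), NK and innate-like (1 higher and 1 lower of 3, median -0.25, mean -0.07, test upward, adjusted p = 0.953) and Y-linked (0 higher and 4 lower of 4, median -1.27, adjusted p = 0.174). Single-gene lists gave Cd8b1 -0.46 (adjusted p = 0.0164), Pecam1 -1.54 and Kit 0.82. Without double-null replicate 1 or replicate 2 the Y-linked list passed (adjusted p = 0.0215 and 0.0219).

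How did double-null cells differ from WT? Double-null cells had the most Th17 cytokine transcript: Il17a rose from 256.4 ± 19.0 to 2497 ± 174 FPKM (log2 fold change 3.28, adjusted p = 3.96e-08, n = 2 per genotype), Il17f from 289 ± 29.0 to 4427 ± 374 (3.94) and Il22 from 22.7 ± 1.94 to 142 ± 27.7 (2.58, adjusted p = 1.95e-07). Ccl20 rose from 75.7 ± 3.42 to 1369 ± 78.9 FPKM (4.16). Il9 rose by 3.71 (adjusted p = 8.04e-08). Type 2 cytokine genes rose as well: Il4 by 2.31, Il13 by 1.14 and Il5 by 1.04 (adjusted p = 0.000685). Ifng fell to 16.9 ± 1.30 FPKM (-5.99, adjusted p = 3.08e-09). In all, 3734 genes were higher and 3775 lower of 10281 tested, and 1324 of these 7509 changed at least 2-fold.

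Further large rises in double-null cells were those of Mmp13 (64.3 FPKM, log2 4.35), Timp1 (20.9, 3.62), Npy, a neuropeptide (12.4 ± 1.67 to 159.6 ± 80.4 FPKM, 3.49, with 103 and 216 in the double-null libraries), and Gzmb (3.40). Il10 (2.23), Il21 (1.65), Il2 (0.98) and Irf4 (0.51) rose, and Csf2 (-1.27), Bcl6 (-1.19), Tbx21 (-3.29) and Stat6 (-1.65) fell. Foxp3 rose by 0.25 (adjusted p = 0.0135), a call lost without WT replicate 1 (adjusted p = 0.0768) and without double-null replicate 2 (adjusted p = 0.0843). Gata3 gave 0.01 (adjusted p = 0.922) and Tnf -0.17 (adjusted p = 0.0697, and 0.0128 without double-null replicate 1). Nkg7, found in cytotoxic granules, fell from 21.5 ± 1.43 to 1.501 ± 0.0968 FPKM (-3.17), Ccr7 from 132 ± 15.0 to 18.8 ± 0.434 (-2.75), and Cxcr3 (-2.80), Arl5c (-2.74), Beta-s (-6.10) and Hba-a1 (-5.71) fell as well.

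As a group, Th17 genes were higher in double-null cells than in WT (14 higher and 1 lower of 15, median 1.68, adjusted p = 2.52e-05). The Th17 list had an adjusted p = 0.712 with an estimated correlation. Interferon response genes were lower (2 higher and 26 lower of 29, median -0.87, adjusted p = 1.72e-05), with Gbp4 at -1.60, Iigp1 at -1.81 and Gbp2 at -1.15, although Ifih1 rose (1.51). The interferon list had an adjusted p = 0.712 with an estimated correlation. Immediate early genes were lower (4 higher and 19 lower of 27, median -0.41, adjusted p = 0.00669), with Fosb at -1.95, Egr3 at -1.92, Nr4a2 at -1.81 and Dusp1 at -1.29. The immediate early list had an adjusted p = 0.712 with an estimated correlation.

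The other lists did not pass in double-null cells against WT. Th2 (11 higher and 4 lower of 16, median 0.65, adjusted p = 0.236) included Areg, a growth factor for epithelium (1.40), and Ccr8 (-2.20), and Th9 (6 higher and 5 lower of 15, median 0.05, adjusted p = 0.872) included Batf (1.59), Irf8 (1.04) and Il17rb (-1.75). Th1 (6 higher and 9 lower of 18, median -0.44, adjusted p = 0.328) included Cxcr6 (1.43), cytotoxic effector (3 higher and 6 lower of 11, median -0.37, adjusted p = 0.295) included Ctsw (-2.48), and Treg (9 higher and 9 lower of 19, median -0.10, mean 0.04, test upward, adjusted p = 0.931) included Socs2 (1.61) and Nrp1 (-1.24). Further lists were Tfh (6 higher and 7 lower of 14, median -0.11, mean 0.25, test upward, adjusted p = 0.886), naive and central memory (4 higher and 10 lower of 16, median -0.55, adjusted p = 0.236) with Cd27 at -1.55, and skin homing and tissue residence (7 higher and 9 lower of 17, median -0.34, adjusted p = 0.454). The response lists were IL-4 and STAT6 (3 higher and 7 lower of 14, median -0.20, adjusted p = 0.295) and IL-2 and STAT5 (11 higher and 3 lower of 16, median 0.54, adjusted p = 0.0955). Cell cycle (2 higher and 12 lower of 29, 2 and 8 adjusted over the list alone, median -0.16, adjusted p = 0.295) and glycolysis (7 higher and 4 lower of 15, median 0.13, adjusted p = 0.454), with Hk2 at 1.87, did not pass either. Stress lists were heat shock (8 higher and 4 lower of 12, median 0.28, adjusted p = 0.295) and the unfolded protein response (8 higher and 2 lower of 12, median 0.26, adjusted p = 0.236) with Asns at 1.34, Chac1 at 1.203 and Sdf2l1 at 0.92. Markers of other cells were B cell (0 higher and 1 lower of 8, median -0.43, adjusted p = 0.343), myeloid (1 higher and 5 lower of 8, median -0.51, adjusted p = 0.245), NK and innate-like (1 higher and 1 lower of 3, median -0.52, adjusted p = 0.931), keratinocyte (2 higher and 1 lower of 3, median 0.70, adjusted p = 0.353) and Y-linked (0 higher and 3 lower of 4, median -1.15, adjusted p = 0.263). Single-gene lists gave Cd8b1 -0.35 (adjusted p = 0.0512), Pecam1 -1.21 and Kit 1.65. Without double-null replicate 2 the IL-2 and STAT5 response (adjusted p = 0.0366), cell cycle (adjusted p = 0.0366) and Y-linked lists (adjusted p = 0.0209) passed.

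What does losing STAT6 add where T-bet is already lost? Against T-bet-null cells, double-null cells had more Il22 (9.68 ± 0.0655 to 142 ± 27.7 FPKM, log2 fold change 3.73, adjusted p = 5.22e-07, n = 2 per genotype), Il17f (2.60) and Il17a (2.05), and less Il5 (279 ± 9.55 to 54.3 ± 0.398 FPKM, -2.34, adjusted p = 5.85e-05), Il4 (-1.500, adjusted p = 0.000324) and Il13 (-1.43). Il9 rose from 7.86 ± 1.27 to 16.03 ± 0.258 FPKM (0.95, adjusted p = 0.00126). With a pseudocount of 0.1 that Il9 call was lost (1.03, adjusted p = 0.052), and apart from the 2-fold limit no other setting lost it. Kit, the stem cell factor receptor also known from mast cells and innate lymphoid cells, rose from 8.39 ± 0.393 to 59.8 ± 4.37 FPKM (2.69). In all, 1688 genes were higher and 1663 lower of 10281 tested, and 133 of these 3351 changed at least 2-fold. The count was 1885 without T-bet-null replicate 1, 1642 without T-bet-null replicate 2 and 1977 without double-null replicate 2.

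Gzmb (16.02 to 153 FPKM, log2 3.11), Ccl20 (2.94), Npy (2.46), Iltifb, a close copy of Il22 (2.35), Coro2a (2.19), Il10 (1.78), Il21 (1.10) and Tbx21 (0.40, adjusted p = 0.00551) were also higher. AA465934 fell back from 35.8 to 1.80 FPKM (-3.72). Cd160, a checkpoint receptor (-1.91), Lrrc32, which anchors TGF-beta on Treg cells (-1.87), Sfi1 (-1.81), the BMP antagonist Sostdc1 (-1.80), Gfi1, a repressor induced by IL-4 (77.7 to 22.8 FPKM, -1.73), Stat6 (-1.63), Gata3 (-0.87) and Ifng (-0.93) fell. Not called were Il2 (0.26, adjusted p = 0.0719), Csf2 (-0.18, adjusted p = 0.259), Tnf (0.17), Foxp3 (0.16), Bcl6 (-0.04) and Irf4 (-0.06). Without double-null replicate 2, Il2 (adjusted p = 0.0153) and Tnf (adjusted p = 0.0462) were called, and without double-null replicate 1 Foxp3 was (adjusted p = 0.0211). Il2 was also called with robust empirical Bayes (adjusted p = 0.0458), and Irf4 with quantile normalization (adjusted p = 0.0109).

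As a group, Th17 genes were higher in double-null than in T-bet-null cells (13 higher and 0 lower of 15, median 1.21, adjusted p = 7.66e-12). The Th17 list had an adjusted p = 0.327 with an estimated correlation. Th2 genes were lower (3 higher and 10 lower of 16, 3 and 12 adjusted over the list alone, median -0.69, adjusted p = 0.000642), among them Ccr8 (-1.35) and Ccr4 (-0.93), while Areg rose (1.34). The Th2 list had an adjusted p = 0.327 with an estimated correlation. IL-4 and STAT6 response genes were lower (1 higher and 6 lower of 14, 2 and 7 adjusted over the list alone, median -0.18, adjusted p = 0.0168), with Ecm1 at -0.78. The IL-4 response list had an adjusted p = 0.674 with an estimated correlation. Th1 genes were higher (10 higher and 3 lower of 18, 11 and 3 adjusted over the list alone, median 0.30, adjusted p = 0.00693), with Havcr2 at 1.34 and Cxcr3 at 0.98, against Ifng in the other direction. The Th1 list had an adjusted p = 0.449 with an estimated correlation.

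Unfolded protein response genes, which serve the load of secreted protein, were higher (10 higher and 1 lower of 12, median 0.43, adjusted p = 0.000198), with Sdf2l1 at 0.90, Herpud1 at 0.65, Pdia4 at 0.58 and Hspa5 at 0.46. The unfolded protein list had an adjusted p = 0.449 with an estimated correlation. Cell cycle genes were higher (10 higher and 1 lower of 29, 13 and 1 adjusted over the list alone, median 0.24, adjusted p = 0.00225), with Aurka at 0.51 and Mcm3 at 0.50. The cell cycle list had an adjusted p = 0.813 with an estimated correlation. IL-2 and STAT5 response genes were higher (8 higher and 2 lower of 16, median 0.23, adjusted p = 0.0111), with Socs3 at 1.05 and Prdm1 at 0.63. Their adjusted p = 0.674 with an estimated correlation and 0.0878 with quantile normalization. All of these list calls were kept in a fit without the WT libraries, chosen after WT was seen to stand apart.

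The other lists did not pass. Th9 (6 higher and 4 lower of 15, median 0.22, adjusted p = 0.496) included Batf (0.76), Smad3 (0.48) and Pparg, a factor of IL-9-producing cells (-1.01), and Treg (8 higher and 7 lower of 19, 10 and 7 adjusted over the list alone, median 0.22, adjusted p = 0.496) included Tigit (0.67) and Nrp1 (-0.79). Interferon response (9 higher and 1 lower of 29, median 0.05, adjusted p = 0.0668) included Gbp5 (0.75). It passed without T-bet-null replicate 2 (adjusted p = 0.0448), without double-null replicate 1 (adjusted p = 0.00756) and with quantile normalization (adjusted p = 0.0238). The heat shock list passed with quantile normalization (adjusted p = 0.0167) and at a filter of 5 FPKM (adjusted p = 0.0381). Next, skin homing and tissue residence (6 higher and 5 lower of 17, 9 and 6 adjusted over the list alone, median 0.16, adjusted p = 0.74) included Itga4 (-1.39). Others were cytotoxic effector (3 higher and 3 lower of 11, median 0.02, mean 0.19, test downward, adjusted p = 0.943), Tfh (6 higher and 2 lower of 14, median 0.04, adjusted p = 0.382), naive and central memory (2 higher and 4 lower of 16, median -0.17, adjusted p = 0.355) and immediate early (6 higher and 3 lower of 27, median -0.02, mean 0.03, test upward, adjusted p = 0.877). Glycolysis (4 higher and 4 lower of 15, 5 and 4 adjusted over the list alone, median 0.11, adjusted p = 0.382), heat shock (0 higher and 4 lower of 12, median -0.13, adjusted p = 0.0872) and B cell markers (0 higher and 0 lower of 8, median 0.15, adjusted p = 0.877) did not pass either. Myeloid markers (2 higher and 1 lower of 8, median 0.24, adjusted p = 0.382) included Lyz2 (1.19), beside NK and innate-like (1 higher and 0 lower of 3, median 0.10, adjusted p = 0.382) and keratinocyte markers (1 higher and 1 lower of 3, median -0.03, adjusted p = 0.943). Y-linked genes (0 higher and 0 lower of 4, median 0.36, adjusted p = 0.433) passed only without double-null replicate 1 (median 0.83, adjusted p = 0.00208). Single-gene lists gave Cd8b1 0.02 (adjusted p = 0.918), Pecam1 0.00 (adjusted p = 0.982) and Hba-a1 -0.56 (adjusted p = 0.252).

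What does losing T-bet add where STAT6 is already lost? Against STAT6-null cells, double-null cells had less Ifng (3610.0 ± 133 to 16.9 ± 1.30 FPKM, log2 fold change -7.66, adjusted p = 5.57e-10, n = 2 per genotype), Cxcr3 (252 ± 2.10 to 16.1 ± 0.518 FPKM, -3.89) and the chemokines Ccl3 (-3.92) and Ccl4 (-2.54), which draw in effector T cells and monocytes. Il17a (2.21, adjusted p = 2.23e-06), Il17f (2.12) and Il22 (2.05) rose, as did Il23r, the receptor that sustains Th17 cells (5.24 ± 1.19 to 22.8 ± 3.12 FPKM, 1.94). Il9 rose from 4.58 ± 0.0564 to 16.03 ± 0.258 FPKM (1.61, adjusted p = 0.000119). In all, 1157 genes were higher and 887 lower of 10281 tested, and 104 of these 2044 changed at least 2-fold. The count was 846 without STAT6-null replicate 1, 1038 without STAT6-null replicate 2 and 1236 without double-null replicate 2.

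Of the type 2 cytokine genes, Il5 rose by 0.97 (adjusted p = 0.00694), while Il4 (-0.79, adjusted p = 0.0112) and Il13 (-0.52, adjusted p = 0.00533) fell. Without STAT6-null replicate 1 the calls of Il4 (adjusted p = 0.0632) and Il13 (adjusted p = 0.0537) were lost, and without STAT6-null replicate 2 those of Il4 (adjusted p = 0.0647) and Il5 (adjusted p = 0.0509). Il4 was also lost without double-null replicate 2 (adjusted p = 0.0564). Il21 fell (-0.40, adjusted p = 0.053 without STAT6-null replicate 2) and Gata3 rose (0.32, adjusted p = 0.0646 without STAT6-null replicate 2). Il2 rose by 0.40 (adjusted p = 0.0231), a call lost without STAT6-null replicate 1 (adjusted p = 0.145), STAT6-null replicate 2 (adjusted p = 0.0907) or double-null replicate 1 (adjusted p = 0.0688), and with only the compared genotypes in the fit (adjusted p = 0.0512).

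Other large rises were those of Npy (2.50), the prohormone-processing enzyme Cpe (2.96 to 20.1 FPKM, 2.41) and Iltifb (1.92). The ribosomal gene Rps27 was called higher (2.73, adjusted p = 0.012), with 404 and 1692 FPKM in the double-null libraries. That Rps27 call was lost with robust empirical Bayes (adjusted p = 0.097), without STAT6-null replicate 1 (adjusted p = 0.0815) and without STAT6-null replicate 2 (adjusted p = 0.0519). Ly6a (-3.15), Iigp1 (-3.10), Nkg7 (-2.80), Csf2 (-2.18), Il10 (-0.76) and Tbx21 (-4.90) fell. Not called were Stat6 (-0.10, adjusted p = 0.302), Tnf (adjusted p = 0.992), Foxp3 (-0.15), Bcl6 (0.18) and Irf4 (-0.12). Bcl6 was called without double-null replicate 1 (adjusted p = 0.0456), Foxp3 without double-null replicate 2 (adjusted p = 0.0469) and Irf4 with quantile normalization (adjusted p = 0.0445).

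As a group, interferon response genes were lower in double-null than in STAT6-null cells (0 higher and 20 lower of 29, 0 and 21 adjusted over the list alone, median -0.69, adjusted p = 4.41e-17), with Irgm1 at -1.72, Gbp4 at -1.48 and Gbp7 at -1.45. The interferon list had an adjusted p = 0.185 with an estimated correlation. Th1 genes were lower (1 higher and 11 lower of 18, 1 and 13 adjusted over the list alone, median -0.53, adjusted p = 1.54e-11). They include the targeted gene Tbx21, and their mean (-1.534) lay below their median, so a few members weigh heavily. The Th1 list had an adjusted p = 0.148 with an estimated correlation. Cytotoxic effector genes were lower (0 higher and 7 lower of 11, 0 and 8 adjusted over the list alone, median -0.49, adjusted p = 1.19e-05), with Ctsw at -1.05 and Serpinb9 at -0.74. The cytotoxic list had an adjusted p = 0.217 with an estimated correlation. Treg genes were lower (0 higher and 12 lower of 19, 0 and 13 adjusted over the list alone, median -0.37, adjusted p = 3.97e-08), with Socs2 at -0.67, Itgae at -0.65, Tnfrsf18 at -0.56 and Tigit at -0.51. The Treg list had an adjusted p = 0.217 with an estimated correlation.

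Th17 genes were higher (13 higher and 2 lower of 15, median 1.63, adjusted p = 1.28e-10), with Ccr6, the receptor of Ccl20, at 1.63. The Th17 list had an adjusted p = 0.185 with an estimated correlation. Cell cycle genes were higher (25 higher and 0 lower of 29, 27 and 0 adjusted over the list alone, median 0.60, adjusted p = 2.42e-14), with Aurka at 0.81, Rrm2 at 0.80 and Mcm3 at 0.67. The cell cycle list had an adjusted p = 0.301 with an estimated correlation. Unfolded protein response genes were higher (7 higher and 0 lower of 12, 8 and 0 adjusted over the list alone, median 0.30, adjusted p = 0.000596), with Sdf2l1 at 0.76, Herpud1 at 0.67 and Asns at 0.67. The unfolded protein list had an adjusted p = 0.301 with an estimated correlation. B cell markers were lower (0 higher and 1 lower of 8, median -0.57, adjusted p = 0.0163), with Cd22 at -0.53. The B cell list had an adjusted p = 0.707 with an estimated correlation. That call was lost without STAT6-null replicate 1 (median -0.07, adjusted p = 0.574), without double-null replicate 2 (adjusted p = 0.0594) and at a filter of 5 FPKM (adjusted p = 0.159). The keratinocyte list was lower (0 higher and 2 lower of 3, median -0.32, adjusted p = 0.025) through Sfn (-1.72) and Dsp (-0.32, adjusted p = 0.0341), with Perp at -0.05. Its adjusted p = 0.222 with an estimated correlation, 0.0568 without double-null replicate 1 and 0.124 with no filter. All of these list calls were kept in the fit without the WT libraries.

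The other lists did not pass. Th2 genes were split (6 higher and 6 lower of 16, 6 and 7 adjusted over the list alone, median -0.07, adjusted p = 0.825), with Ccr4 at 0.98, Areg at 1.27 and Ccr8 at -0.87. Th9 genes were too (3 higher and 2 lower of 15, 3 and 3 adjusted over the list alone, median -0.05, mean 0.10, test downward, adjusted p = 0.771), with Il9r at 0.56 and Irf8 at -0.45. Others were Tfh (2 higher and 4 lower of 14, 4 and 5 adjusted over the list alone, median -0.03, adjusted p = 0.478), naive and central memory (4 higher and 2 lower of 16, median -0.01, mean 0.00, test downward, adjusted p = 0.973) with Ccr7 at -0.95, and skin homing and tissue residence (6 higher and 3 lower of 17, median 0.11, adjusted p = 0.723). IL-4 and STAT6 response (3 higher and 4 lower of 14, 4 and 4 adjusted over the list alone, median -0.08, adjusted p = 0.587), IL-2 and STAT5 response (2 higher and 4 lower of 16, 3 and 5 adjusted over the list alone, median -0.07, adjusted p = 0.144) and immediate early genes (4 higher and 6 lower of 27, median -0.07, adjusted p = 0.343) did not pass. Glycolysis (2 higher and 2 lower of 15, 3 and 2 adjusted over the list alone, median 0.06, adjusted p = 0.723), heat shock (1 higher and 0 lower of 12, median -0.01, mean 0.00, test upward, adjusted p = 0.99), myeloid markers (0 higher and 2 lower of 8, 0 and 3 adjusted over the list alone, median -0.17, adjusted p = 0.0856) and NK and innate-like markers (0 higher and 0 lower of 3, median -0.12, adjusted p = 0.478) did not either. Without STAT6-null replicate 2 the immediate early (adjusted p = 0.0196) and myeloid lists (adjusted p = 0.0341) passed downward, and the myeloid list did so without double-null replicate 2 (adjusted p = 0.00658). Y-linked genes (0 higher and 0 lower of 4, median 0.23, adjusted p = 0.754) passed upward without double-null replicate 1 (median 0.70, adjusted p = 0.00114) and downward without double-null replicate 2 (median -0.31, adjusted p = 0.0174). Single-gene lists gave Cd8b1 0.11 (adjusted p = 0.62), Pecam1 0.33 (adjusted p = 0.00911), Kit 0.83 and Hba-a1 -0.12 (adjusted p = 0.848).

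Does the same loss do the same thing in both backgrounds? Il17a, Il17f, Il10 and Il21 rose with STAT6 loss whether T-bet was present or not, whereas Ifng rose with T-bet present (1.67) and fell without it (-0.93). Il4 (3.09 and -1.50) and Il13 (1.66 and -1.43) likewise rose with T-bet present and fell without it. Over all 10281 genes the effects of STAT6 loss in the 2 backgrounds had r = 0.382 (Spearman 0.351). Of the genes called in both, 1014 were higher in both (589.6 if independent), 977 lower in both (599.9), 270 higher with T-bet and lower without (580.9) and 267 the reverse (609). For T-bet loss, Cxcr3 and Ifng fell and Il9, Il17a and Il17f rose in both backgrounds. Some other core genes changed direction. Il4 (3.81 and -0.79), Il13 (2.57 and -0.52), Il10 (0.45 and -0.76) and Il21 (0.55 and -0.40) rose with STAT6 present and fell without it. Il22 (-1.15 and 2.05) did the reverse. The falls of Il4, Il13 and Il21 were not called under every setting. Over all genes, the effects of T-bet loss had r = 0.255 (Spearman 0.238). There 617 genes were higher in both (395.9 if independent), 519 lower in both (322.4), 178 higher with STAT6 and lower without (303.5) and 318 the reverse (420.6). No libraries are shared between the comparisons of a pair. In each pair, the comparison with the partner factor present is against WT and so holds the shift of WT as well.

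**Figure D3:**
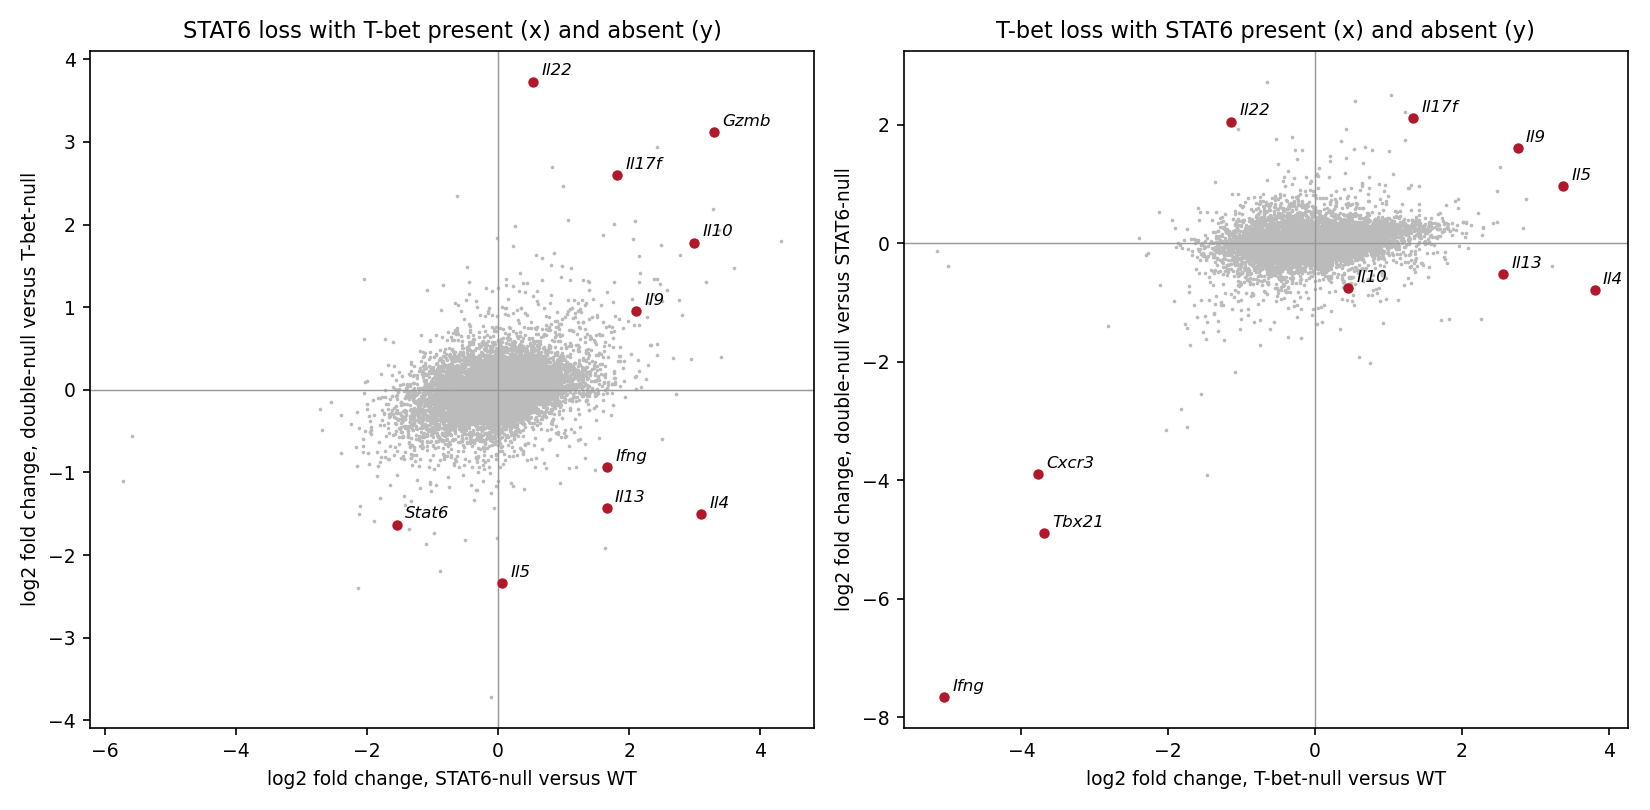
Log2 fold change of each of 10281 genes on STAT6 loss (left) and T-bet loss (right), with the partner factor present on the x axis and absent on the y axis. Il4 lies at 3.09 and -1.500 on the left, and r is 0.382 on the left and 0.255 on the right.

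Transcripts outside the helper cell programmes also separated the libraries. Summed haemoglobin transcript was 441.9 and 223.71 FPKM in the WT libraries and 2.63 to 7.48 in the mutants. Ddx3y, a Y-linked gene, stood at 60.1 and 66.0 FPKM in WT, 16.3 and 15.8 in T-bet-null, 21.3 and 19.1 in STAT6-null and 16.2 and 36.6 in double-null libraries. Eif2s3y followed at 32.8 and 31.2, 14.5 and 14.7, 18.0 and 14.5 and 10.5 and 24.0. The B cell and antigen-presenting cell gene Cd74 stood at 59.8 and 37.5, 34.7 and 32.9, 105 and 45.5 and 42.3 and 47.8 FPKM, and the myeloid gene Lyz2 at 12.2 and 7.85, 2.49 and 3.59, 13.1 and 13.6 and 6.52 and 10.02. Of the sorting markers, Cd4 stood at 195 and 208, 122 and 114, 127 and 127 and 88.1 and 110.1, and Cd44 at 251 and 282, 436 and 442, 355 and 357 and 389 and 362.

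**Figure D4:**
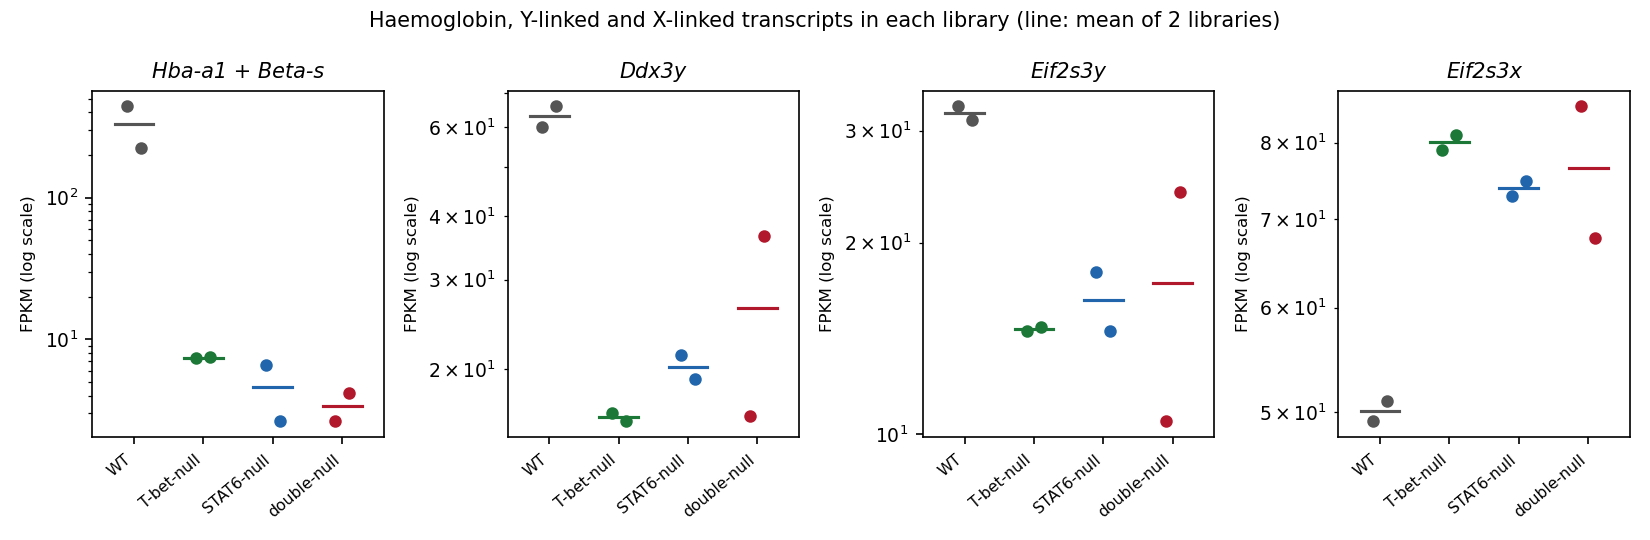
FPKM (log axis) of summed haemoglobin, Ddx3y, Eif2s3y and the X-linked Eif2s3x in each library by genotype. Haemoglobin and Y-linked transcripts are highest in WT, and the 2 double-null libraries differ in Ddx3y (16.2 and 36.6 FPKM).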

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

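What flagged each value in this part is a difference between groups: the test of interaction, which asks whether STAT6 loss changes a gene by a different amount in T-bet-null than in T-bet-sufficient cells. Negative values mean a lower double-null level than the single mutants' log2 changes would add up to. Of 10281 genes tested, 5889 were called (3046 positive, 2843 negative), 852 of them at 2-fold or more. A gene that shifts alike in all 3 mutants gets an interaction opposite to that shift by arithmetic. In all, 5575 genes were called in the same direction in all 3 mutants. How many of the 5889 calls arise in this way was not counted, and such calls need no joint action of the losses.

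Type 2 cytokine genes had negative values. Il4, the lowest of the core genes, was raised by either loss, yet double-null cells (729 ± 25.3 FPKM) stood below both single mutants, with an interaction of -4.59. Il13 (-3.09) and Il5 (-2.40) were negative too, as was Il3, which supports mast cells and basophils (22.1, 80.5, 129 and 55.2 FPKM in WT, T-bet-null, STAT6-null and double-null cells, -3.10). Ifng (-2.60), Il10 (-1.21), Tbx21 (-1.2), Il9 (-1.15), Csf2 (-1.09), Il21 (-0.95), Irf4 (-0.68) and Gata3 (-0.56) had negative values as well. Tbx21 is itself the targeted gene in T-bet-null and double-null cells, so its value follows at least in part from the design. It is also a member of the Th1 list tested below. Positive values belonged to Il22 (3.20), its copy Iltifb (2.98), Bcl6 (1.33), Il17a (0.98), Il17f (0.78) and Tnf (0.34, adjusted p = 0.0261). The Tnf call was lost without WT replicate 2 (adjusted p = 0.0596), T-bet-null replicate 1 (adjusted p = 0.0576), T-bet-null replicate 2 (adjusted p = 0.094), STAT6-null replicate 2 (adjusted p = 0.0965) or double-null replicate 1 (adjusted p = 0.0602), with quantile normalization (adjusted p = 0.695) and with the GC and length trends removed (adjusted p = 0.213). Il2 (-0.32) and Foxp3 (-0.24) were not called, except Il2 without double-null replicate 1 (adjusted p = 0.00768) and Foxp3 without double-null replicate 2 (adjusted p = 0.0111) and under some other settings, among them the GC and length trends removed (adjusted p = 0.0115).

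For Il9 the sign depends on the scale. In FPKM the double-null rise over WT (15.72) exceeded the sum of the single rises (11.82) by 3.9, while the log2 interaction was -1.15 and kept its sign and call with pseudocounts of 0.25 and 0.1.

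Other genes with the largest values were AA465934 (-3.61), the checkpoint receptor gene Cd160 (-3.54), Sema7a (-3.01) and Foxb1 (-2.76) on the negative side. On the positive side were Hba-a1 (5.03), Beta-s (4.61), Rps27 (3.39), the relaxin gene Rln3 (2.66), Mxd4 (2.49) and Sytl1 (2.40). Hba-a1, Beta-s, Mxd4 and Sytl1 were lower in all 3 mutants than in WT, so that a fall that occurs once and does not occur again counts as a positive interaction. The same holds for Bcl6, lower in all 3 mutants and not called in the main fit between double-null cells and either single mutant. The immediate early list was also lower in all 3 mutants, and its double-null medians were -0.02 against T-bet-null and -0.07 against STAT6-null cells. Irf4 is the mirror case, higher in all 3 mutants and not called in the main fit between double-null cells and either single mutant. Its negative interaction therefore needs no joint action of the losses. The Rps27 call was lost with robust empirical Bayes (adjusted p = 0.0659).

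Lists with a median interaction past the camera test were cell cycle (0.95, 29 higher and 0 lower of 29, adjusted p = 4.24e-09), immediate early (0.60, 19 higher and 2 lower of 27, adjusted p = 0.00134) and Th17 (0.78, 11 higher and 2 lower of 15, adjusted p = 0.0215). The unfolded protein response (0.34, 9 higher and 0 lower of 12, adjusted p = 0.0215) was positive as well. Cell cycle medians against WT were -0.30 in T-bet-null, -0.67 in STAT6-null and -0.16 in double-null cells. Part of that list's interaction may thus arise from the shift away from WT. The cell cycle list was however also higher in double-null than in T-bet-null (median 0.24) and STAT6-null cells (0.60). Negative were the 3 keratinocyte-list genes (-1.59, adjusted p = 0.0215), Th2 (-0.45, 3 higher and 10 lower of 16, adjusted p = 0.0384), heat shock (-0.39, 1 higher and 6 lower of 12, 3 and 7 adjusted over the list alone, adjusted p = 0.0498), Th1 (-0.37, 5 higher and 9 lower of 18, 6 and 9 adjusted over the list alone, adjusted p = 0.0384) and Treg (-0.24, 2 higher and 9 lower of 19, adjusted p = 0.038). With an estimated correlation none passed (adjusted p = 0.618 for cell cycle and 0.627 for Treg). Lists that did not pass included interferon response (13 higher and 4 lower of 29, median 0.34, adjusted p = 0.123), naive and central memory (10 higher and 4 lower of 16, 11 and 4 adjusted over the list alone, median 0.52, adjusted p = 0.0759), Th9 (5 higher and 5 lower of 15, median -0.10, adjusted p = 0.798) and Y-linked genes (4 higher and 0 lower of 4, median 1.57, adjusted p = 0.0759).

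Some of these lists lie close to the threshold. Heat shock, with a median of -0.39 and an adjusted p = 0.0498, kept medians of -0.392 to -0.419 and was no longer called without WT replicate 1 (adjusted p = 0.0596), WT replicate 2 (adjusted p = 0.0542), T-bet-null replicate 1 (adjusted p = 0.0518) or double-null replicate 2 (adjusted p = 0.0575), and Th1 without WT replicate 1 (median -0.373, adjusted p = 0.0596). With median-of-ratios scaling heat shock was not called either (median -0.411, adjusted p = 0.0529). At a filter of 5 FPKM, Th2 (adjusted p = 0.063), heat shock (adjusted p = 0.063) and Treg (adjusted p = 0.0837) were lost, as was the keratinocyte list with no filter (adjusted p = 0.0524). Gained were naive and central memory without STAT6-null replicate 1 (adjusted p = 0.0344), interferon response without double-null replicate 1 (adjusted p = 0.0329), and Y-linked genes without double-null replicate 1 (adjusted p = 0.0041) or replicate 2 (adjusted p = 0.0158).

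The wide interaction goes with a shift of all 3 mutants away from WT, and its explanations were weighed by tests of which those on haemoglobin and on male cells were chosen only after the result was seen. GC content and transcript length held 1.67% of the variance of the mean mutant change, and after their trend was removed 4758 of the 5069 genes changed in all 3 mutants that have known GC content and length were kept (93.9%), which argues against a length or GC bias. Red blood cell RNA was at most 0.095% of summed FPKM, which argues against its displacing other transcripts. For male cells in WT, double-null replicate 2 lay 0.534 of the way from replicate 1 to WT in Y-linked genes (0.295 to 0.987 over 4 genes) and moved with a slope of 0.011 in the shifted genes (SD 0.0027 over 1000 resamples of genes, not of samples), which rests on 1 library and excludes nothing. A different male share, a batch of its own for WT and a true effect of either loss all remain possible, since the labels give neither sex nor batch and no value here separates them.

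Y-linked transcripts formed the other pattern, and both tests on them were chosen only after the result was seen, while that on X-linked genes was written before. The 4 genes were 1.69 to 4.77 times lower in mutants than in WT by genotype means, and 2.27 to 2.81 times higher in double-null replicate 2 than in replicate 1. A mixture of male and female cells would lower all 4 by 1 common factor. Between WT and T-bet-null cells their log2 ratios ranged over 1.13, which argues against a mixture as the sole cause, though reads shared with the X-linked copies were not tested. Between the double-null libraries the range was 0.31. All 4 X-linked genes that escape inactivation were lower in double-null replicate 2 than in replicate 1. In replicates 1 and 2 Eif2s3x stood at 85.23 and 67.75, Kdm5c at 25.23 and 19.95, Kdm6a at 13.16 and 8.78 and Ddx3x at 295.91 and 257.08 FPKM. A different male share may thus contribute between these libraries. From WT to the mean of the mutants the X-linked genes had a median change of 0.25 (Eif2s3x 0.604, Kdm5c 0.356, Kdm6a 0.151, Ddx3x -0.106), so a different male share may contribute to that difference too.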

How the results depend on the processing

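Il4, Il5, Il13, Ifng, Il17a and Il17f kept direction and call in each comparison with WT in which they were called, under every alternative. Over all settings, the core genes and the genes named for the largest changes gave 4517 results that were the same, 61 weaker, 24 stronger and none reversed. The genes beyond the core set were chosen for large changes in these same data, which favours such stability. For lists, 2192 were the same, 59 weaker, 24 stronger and 1 reversed. Lists that neither fit called count as the same and make up much of that number. The estimated correlation alone gave 37 of the weaker results, and no list call was kept under it. Changes of sign in values that neither fit called count as the same. The reversed result was the Y-linked list in double-null against STAT6-null cells: its median was -0.306 without double-null replicate 2 and 0.696 without replicate 1, where the unequal Y-linked levels of those libraries show the cause.

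Counts of called genes were within 1.5 times the reported count except as follows. Leaving out each library in turn gave 1642 to 3317 genes for double-null against T-bet-null cells (1885 without T-bet-null replicate 1, 1642 without replicate 2, 1977 without double-null replicate 2). For double-null against STAT6-null cells the range was 846 to 2057 (846 without STAT6-null replicate 1, 1038 without replicate 2, 1236 without double-null replicate 2). The lone library left in a genotype is then assumed to vary like the others. All of the libraries named here belong to a compared genotype, which is then left with 1 library, and this by design tends to lower the count. Why leaving out double-null replicate 2 lowered the counts more than leaving out replicate 1 was not tested. The added 2-fold limit left 856, 1039, 1324, 133, 104 and 852 genes in the order of the comparisons, with the interaction last, by its own construction.

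The other leave-one-out ranges were 6148 to 7437 for T-bet-null, 6428 to 7442 for STAT6-null and 6850 to 7396 for double-null cells against WT, and 4992 to 5749 for the interaction. The correlation between backgrounds stayed at 0.34 to 0.406 for STAT6 loss and 0.207 to 0.287 for T-bet loss. Other settings, without the 2-fold limit, gave 5436 to 7840, 5432 to 7825, 5606 to 8006, 2709 to 4327, 1424 to 2817 and 4532 to 6667 genes. Median-of-ratios scaling or quantile normalization moved the share of higher genes by less than 10 points in every comparison.

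Among alternatives chosen after seeing the data, the fit without WT libraries called 3317 genes for double-null against T-bet-null and 2050 against STAT6-null cells. Without Y-linked and haemoglobin genes 5889 interaction genes were called. With the GC and length trends removed 5607 were called of 9304 genes with known GC content and length, so that count differs in its genes as well as in the trend.

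The replicate number as a block gave 7151, 7219, 7430, 3091, 1836 and 5752 genes. Replicate numbers share only a label, and the differences between replicates 1 and 2 had correlations of -0.09 to 0.091 between genotypes, so no pairing was seen. Depth limits the low genes: Il9 in WT rests on 1 and 4 steps.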

Other observations

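Of 10281 genes, 410 were called higher and 296 lower in double-null cells than in each other genotype. Th17 genes made up 12 of those highest genes out of 15 tested (one-sided Fisher exact test, adjusted p = 1.24e-13), and unfolded protein response genes 6 of 12 (adjusted p = 3.21e-05), while 6 of 19 Treg genes were among the lowest (adjusted p = 0.000236). Fisher's test takes the members as independent, and with an estimated correlation in camera none of these lists passed: the adjusted p was 0.712, 0.327 and 0.185 for Th17 against WT, T-bet-null and STAT6-null cells, 0.449 and 0.301 for the unfolded protein response against the single mutants (0.712 against WT), and 0.969, 0.889 and 0.217 for Treg against WT, T-bet-null and STAT6-null cells. Even with the preset correlation, the unfolded protein response (adjusted p = 0.236) and Treg lists (adjusted p = 0.931) did not pass against WT. Against T-bet-null cells the Treg list had a positive median (8 higher and 7 lower of 19, 10 and 7 adjusted over the list alone, median 0.22, adjusted p = 0.496). Singled out after their values were seen, Areg, which acts on epithelium and Treg cells, stood at 236 ± 7.80, 245 ± 2.44, 257 ± 11.1 and 625 ± 80.0 FPKM in WT, T-bet-null, STAT6-null and double-null cells (n = 2 each), and Ccr6 at 25.6 ± 3.10, 41.6 ± 0.00240, 26.6 ± 0.446 and 84.4 ± 1.85. Esm1 (145 FPKM) and Tnfrsf8, which encodes CD30 (8.29 FPKM), were also highest there.

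Il31, the itch cytokine, followed Il5 rather than Il9: it stood at 1.39 ± 0.159, 12.4 ± 0.291, 2.18 ± 0.804 and 4.81 ± 0.373 FPKM in the same order (log2 2.48 in T-bet-null and -1.203 from T-bet-null to double-null cells). Of 44 cytokine and chemokine genes chosen by symbol after the data were seen, the highest mean was in WT for 14, in T-bet-null for 6, in STAT6-null for 14 and in double-null cells for 10. Cell surface Tnfsf8 was at 451, 847, 1350.4 and 1347 FPKM, and Ccl1 at 299, 261, 764 and 253.

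A hypothesis written before the result was seen held that genes near a targeted locus change more often, through a passenger segment or a regional effect. Within 10 Mb of Stat6, 12 of 91 genes were called with a change of at least 0.5 (log2) in double-null against T-bet-null cells, against 771 of 10105 elsewhere (odds ratio 1.84, Fisher exact one-sided p = 0.045), which fits. Neither this p-value nor that for Tbx21 below was adjusted for the testing of both loci. Fisher's test also takes neighbouring genes as independent, so the fit is weak. Without Ifng, Il22 and Iltifb, a choice made after the result was seen, 9 of 88 remained (odds ratio 1.38, one-sided Fisher exact p = 0.23). Only called genes near Stat6 were taken out and none elsewhere, which lowers the odds ratio by construction. Whether the signal rests on that cytokine cluster is therefore not decided. Near Tbx21, 15 of 203 genes changed in double-null against STAT6-null cells, against 504 of 9993 (odds ratio 1.5, Fisher exact one-sided p = 0.0941), which leaves the question open.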
